A study of Mus musculus with 2 samples.

How the data were processed

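Chromatin immunoprecipitation with sequencing (ChIP-seq) for histone H3 acetylated at lysine 9 (H3K9ac), a histone mark found at active promoters, was carried out on mouse lung at embryonic day 14.5. The labels describe 2 biological replicates of 1 group. Replicate 1 was pooled from the lungs of 24 embryos and replicate 2 from those of 34 embryos, and both pools held males and females. The labels give no second tissue, stage or treatment, so no comparison between groups was possible.

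The deposited data used here were 4 peak lists in narrowPeak format with mm10 coordinates. Per the descriptions deposited with them, the authors called one list on each replicate alone and one on both replicates together, here called the pooled list. A further list of replicated peaks was derived by the authors from the other 3 lists. Each deposited peak has a ratio called its enrichment, which is the authors' own value per peak, and a p-value and a q-value given by the authors as −log10. Per the same descriptions, peaks were called from filtered alignments and 2 further files whose kind is not named. The aligner, the peak caller, its threshold, the overlap rule behind the replicated list and the quantity that the enrichment is relative to are not given in the sources used here. The highest p in any of the 4 lists was 0.00993. The lists hold no read counts, so sequencing depth is unknown and no interval on a single peak could be computed. A gene without a peak therefore has no call in these lists, which is not a measurement of no acetylation.

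Gene positions came from the GENCODE release M21 annotation of mm10, limited to 21853 protein-coding genes with 54361 distinct protein-coding transcript starts on chromosomes 1 to 19, X and Y. A promoter peak overlapped, by at least 1 bp, the window from 1 kb upstream to 1 kb downstream of any of these starts. A peak that touched no such window was called distal and was assigned to the nearest start within 100 kb. The covered length of a gene was the largest number of bases covered by peaks within 5 kb either side of one of its starts, and the broad class was the 5% of genes with the longest covered length. Peaks were analysed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. Coordinates are 1-based.

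The design of each test, 24 gene lists of cell types and pathways, 8 gene families defined by symbol, and the alternatives were set before the data were examined, except where a later choice is named. The share of members with a promoter peak was tested for each list and family against all other protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 32 lists and families and a threshold of 0.05. The share of members in the broad class was tested in the same way among genes with a promoter peak, over the 31 lists and families that had such a gene. The mean number of distal peaks per gene was compared, for the 24 lists, with 10000 random gene sets of the same size matched on decile of the span that a gene could be assigned (permutation test, two-sided, Benjamini-Hochberg adjustment over lists). Overlap between lists was taken as at least 50% of the length of a peak, and was compared with 1000 random placements of the other list on the same chromosomes outside stretches of N (permutation test, one-sided). The difference between replicates was described by the median log2 ratio of replicate 2 to replicate 1 over list members with a promoter peak in both, as a percentile among 10000 matched random sets, with no p. Peaks and genes are not independent replicates, and with 1 library per pool these percentiles describe the 2 libraries.

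The functions were tested on simulated data before use, with lists of 20 genes. For the promoter, broad and distal tests, simulated promoter peaks lay around real transcript starts. Simulated distal peaks were placed at random and more densely around the planted genes. For gene lists at promoters, run over 21853 genes, 50 of 50 lists with a raised share and 48 of 50 with a lowered share were recovered, and 1 of 100 unchanged lists was called. For broad domains, run over 11966 genes, 42 of 50 were recovered and 0 of 150 unchanged lists were called. For distal peaks, over 21853 genes, 47 of 50 were recovered and 2 of 150 unchanged lists were called. The difference between replicates was simulated without peaks, as a random gain per gene unrelated to the value used for matching. By the mean gain, not the median log2 ratio, 19 of 20 planted lists lay outside the middle 95%, as did 6 of 100 unchanged ones. This does not show how often unchanged lists would fall outside it in the real peak lists. For the overlap of lists, a planted share of 59.7% was found as 59.9% over 29989 simulated peaks placed at random.

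The genes named were set by rule: 25 key genes of lung development and of tissues outside it, the 2 members of each list with the strongest promoter peak and the first 2 by alphabet without one, the 10 genes with the strongest promoter peaks, the longest covered length or the most distal peaks, and the 3 strongest distal peaks. Where a list had 3 or fewer members with a peak, or without one, all of these came under the rule. Genes named outside this rule are described as chosen after their values were seen. The alternatives varied the promoter window, the transcript starts, the peak list, the q threshold, the overlap that counts as shared, the replicate used, the breadth class and window, the distal limit and the background of the tests. 6 replicated peaks on sequences outside the 21 reference chromosomes were left out of all gene analyses.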

Results

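H3K9ac ChIP-seq peaks were analysed in mouse lung at embryonic day 14.5, when the epithelium is branching and its tips hold progenitor cells. The group held 2 biological replicates, each a pool of embryos. The peak list of replicate 1 held 54138 peaks covering 32.4 Mb, and that of replicate 2 held 57558 peaks covering 35.7 Mb. The pooled list held 46486 peaks and the replicated list 30472, with median widths of 397 and 725 bp. Sequencing depth is unknown, since the lists give no read counts. The values below are enrichments of the strongest promoter peak in the replicated list, followed in parentheses by those in the lists of replicates 1 and 2. They are the authors' values, and there is 1 value per list, so no SD is given.

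Which gene lists of lung cell types carry the mark was asked first. The labels name no sorting of cells, so a peak cannot be placed in a cell type. Some genes stand in several lists. Sox9 is in the distal tip and cartilage lists, Wnt2b in those of mesenchyme and mesothelium, and Ptch1 in those of mesenchyme and signalling. All 17 genes of the distal tip epithelium list had a replicated promoter peak, against 63.0% of other protein-coding genes (Fisher's exact test, adjusted p = 0.000993). Nkx2-1, a transcription factor required for lung epithelial identity, lay under a peak at chromosome 12, 56525577 to 56538467, with an enrichment of 22.4 (20.4 and 18.0 in the replicates). Sox9, a regulator of tip progenitors, had 14.3 (13.0 and 14.5). Foxa2, an endodermal regulator, had 11.4 (12.8 and 12.4). Fgfr2, the epithelial receptor for FGF10, had 31.8 (24.5 and 34.8), and this peak also touched a start of Ctbp2. Spry2, an inhibitor of FGF signalling, had 31.4 (24.5 and 33.1). The ligands Shh and Bmp4 had 13.5 (10.5 and 14.0) and 15.4 (12.8 and 15.5). Of the 22 pan-epithelial genes, 21 had a promoter peak (adjusted exact p = 0.00114, same test), led by Grhl2 with 15.3 (13.9 and 14.0) and Prom1 with 14.5 (12 and 14.8). The exception was Ehf, with a peak of 3.80 in replicate 1 alone.

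Genes of differentiated airway and alveolar cells were examined next. Of 18 proximal airway genes 5 had a promoter peak, a share of 27.8% that was lower than in other genes (odds ratio 0.226, 95% interval 0.063 to 0.675, adjusted p = 0.00375, Fisher's exact test). These 5, named in full after their values were seen, were Ccdc78, Foxj1, Sox2, Ascl1 and Calca. Foxj1, a regulator of ciliated cells, had 10.7 (9.60 and 11.8), and Sox2, a regulator of proximal epithelium, had 8.10 (6.50 and 8.49). The peak of Ccdc78, with 14.8 (11.1 and 16.4), also touched a start of Haghl. No replicated promoter peak was found at Scgb1a1, which encodes the secretoglobin of club cells, nor at Cdhr3. Bpifa1 had a peak of 2.93 in replicate 2 alone. Of 18 mature alveolar genes 10 had a promoter peak, with no difference from other genes detected (adjusted exact p = 0.668). Lpcat1, an enzyme of surfactant lipid synthesis, had 23.7 (20.1 and 24.0), and the lipid transporter gene Abca3 had 14.1 (10.5 and 15.7) in a peak shared with Abca17. Sftpc, the surfactant protein C gene, had no replicated promoter peak and 2.85 in replicate 2 alone. Within 5 kb of its start 2.26 kb lay under replicated peaks, but no distal peak was assigned to Sftpc. These peaks therefore touched a promoter window of another gene or lay nearer to another gene's start. Cxcl15 and Lamp3 had none in any list of a replicate. Among genes in the same tercile of promoter CpG content, neither the lower share of proximal airway genes (adjusted exact p = 0.301) nor the higher share of distal tip genes (adjusted p = 0.614) passed the test. All distal tip genes had a peak, so their list could not have scored higher in this stratified test, which decides nothing for it.

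Mesenchymal genes carried the mark at their promoters. All 26 lung mesenchyme genes had a replicated promoter peak (adjusted p = 2.63e-05, Fisher's exact test), and all 16 smooth muscle and pericyte genes did (adjusted p = 0.00145). Ptch1, the receptor for Sonic hedgehog, had 40.8 (31.9 and 43.9) in a peak at chromosome 13, 63559105 to 63573973. Tbx3 had 37.0 (28.5 and 38.6). The T-box genes Tbx4 and Tbx5, which are expressed in lung mesenchyme, had 31.2 (26.0 and 30.7) and 30.6 (26.8 and 32.3). Foxf1, a mesenchymal target of hedgehog signalling, had 19.9 (15.1 and 22.1), Pdgfra 12.2 (11.6 and 19.6), Wnt2 12 (10.8 and 12.9) and Fgf10 8.82 (8.77 and 8.53). Among smooth muscle genes Smtn had 15.5 (9.31 and 14.3), Notch3 15.3 (15.2 and 15.5) and Acta2 7.75 (6.98 and 9.01). Of 24 extracellular matrix genes 21 had a peak (adjusted exact p = 0.0135), with Fbn2 at 32.8 (26.6 and 33.9) and Fbln1 at 24.0 (17.9 and 26.1) and no replicated peak at Lum, Mfap5 and Postn. These lists also stood above other genes within terciles of CpG content (adjusted p = 0.0316 for mesenchyme, 1.28e-10 for smooth muscle and 2.76e-09 for matrix, stratified exact test).

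Endothelial genes were marked in 23 of 26 cases (adjusted p = 0.009, Fisher's exact test). Fli1 had 23.2 (17.7 and 24.6), Kdr, a VEGF receptor gene, 9.27 (7.43 and 12.3) and Pecam1 6.15 (4.94 and 6.40), while Gja5 had 16.8 (13.9 and 16.7) in a peak shared with Gpr89. The 3 without a replicated peak were Lyve1, Tie1 and Vwf, of which the latter pair had one in replicate 2 alone. With the 5′ end of each gene as its single start, the endothelial share was 80.8% and missed the threshold (adjusted exact p = 0.0510). Cartilage genes had a peak in 14 of 16 cases (adjusted exact p = 0.0781), and in 93.8% of cases in the list of replicate 2, where they passed (adjusted p = 0.0209), with Sox6 at 15.1 (13.1 and 14.6) and Col2a1 at 6.08 (5.26 and 6.73). Mesothelial genes had one in 6 of 10 (adjusted exact p = 1), with Wnt2b at 7.63 (7.09 and 7.51) and Wt1 at 4.74 (3.10 and 6.73). Genes for ligands, receptors and effectors of FGF, WNT, BMP, hedgehog and retinoic acid signalling had a peak in 48 of 50 cases (adjusted exact p = 2.86e-07), and Smo, which transduces the hedgehog signal, had 37.3 (28.5 and 40.1). The exceptions were Cyp26a1 and Wnt3a. The signalling list missed the threshold within CpG terciles (adjusted exact p = 0.0682).

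In the lists set beforehand, genes of blood and of other organs mostly had no replicated promoter peak. Promoter peaks were found at 5 of 27 blood and immune genes (adjusted p = 8.29e-06, lower than other genes), 5 of 20 neural and neural crest genes (adjusted p = 0.00114), 3 of 15 skeletal muscle genes (adjusted p = 0.00130), 2 of 20 liver genes (adjusted p = 4.28e-06), 3 of 16 genes of gut, stomach and pancreas (adjusted p = 0.000725) and 2 of 23 germline and pluripotency genes (adjusted p = 3.17e-07), all by Fisher's exact test. The albumin gene Alb, the globin gene Hba-a1, the leukocyte gene Ptprc and Phox2b, a regulator of autonomic neurons, had no promoter peak in any list of a replicate. Both liver genes with a peak shared it with another gene: Apoh, with 10.1 (8.65 and 13.5), with Prkca, and Trf, with 4.35 (2.97 and 4.55), with Gm20425. The strongest skeletal muscle peak, 17.3 (13.9 and 17.0) at Actn3, was shared with Zdhhc24, and the strongest germline peak, 17.8 (16.3 and 14.0) at Tex14, with Rad51c. Peaks that touched starts of a single gene included Klf1, an erythroid regulator, with 18.5 (15.8 and 18.1), Runx1 with 15.8 (12.6 and 16.1), Erbb3 with 8.43 (8.67 and 7.61), Barx1 with 6.25 (6.81 and 5.27) and Dazl with 10.3 (8.05 and 11.1). Among all 13768 genes with a promoter peak, 19.0% shared the strongest one with another protein-coding gene. The lower shares of blood and skeletal muscle genes missed the threshold within CpG terciles (adjusted exact p = 0.282 and 0.161). The neural share was 45% in the list of replicate 1 (adjusted exact p = 0.118), 35% in that of replicate 2 and 50% in the pooled list (adjusted exact p = 0.196). That of skeletal muscle was 26.7% in replicate 1 and 40% in replicate 2, where it missed the threshold (adjusted exact p = 0.0662). Blood and immune genes stood at 33.3% and 29.6% in the lists of replicates 1 and 2 and liver genes at 20% and 15%, below other genes in each (highest adjusted exact p = 0.00282). The low share of the first blood list was not seen in a second list of red blood cell genes. In second lists, composed after the first had been examined, a replicated promoter peak was found at 21 of 28 red blood cell genes. The numbers were 13 of 27 for skeletal muscle genes and 2 of 29 for hepatocyte genes. These shares were not tested against other genes or within CpG terciles, and shared peaks were not examined. The red blood cell genes without a replicated promoter peak were Epb42, Spta1, Rhag, Kel, Trim10, Slc25a37 and Car1.

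No difference from other genes was detected for cardiac muscle genes, with 11 of 17 (adjusted p = 1), or thyroid genes, with 4 of 9 (adjusted p = 0.349, Fisher's exact test). At q of 1e-05 or below the thyroid share was 22.2% and below other genes (adjusted exact p = 0.0407). The strongest cardiac peak, 36.5 (28.2 and 38.1) at Myl4, also touched a start of Cdc27, and the next was Ryr2 with 9.61 (7.43 and 10.8). Nkx2-5, a cardiac transcription factor, had 3.65 in the replicated list, no peak in replicate 1 and 5.51 in replicate 2. The list of replicate 2 had promoter peaks at 13 of the 17 cardiac genes and that of replicate 1 at 9. Within CpG terciles the cardiac share lay above other genes (odds ratio 3.34, adjusted exact p = 0.0467). Among thyroid genes Tshr had 13.5 (11.4 and 12.8) in a peak shared with Cep128, and Hhex had 11.1 (7.74 and 12). 

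**Figure D1:**
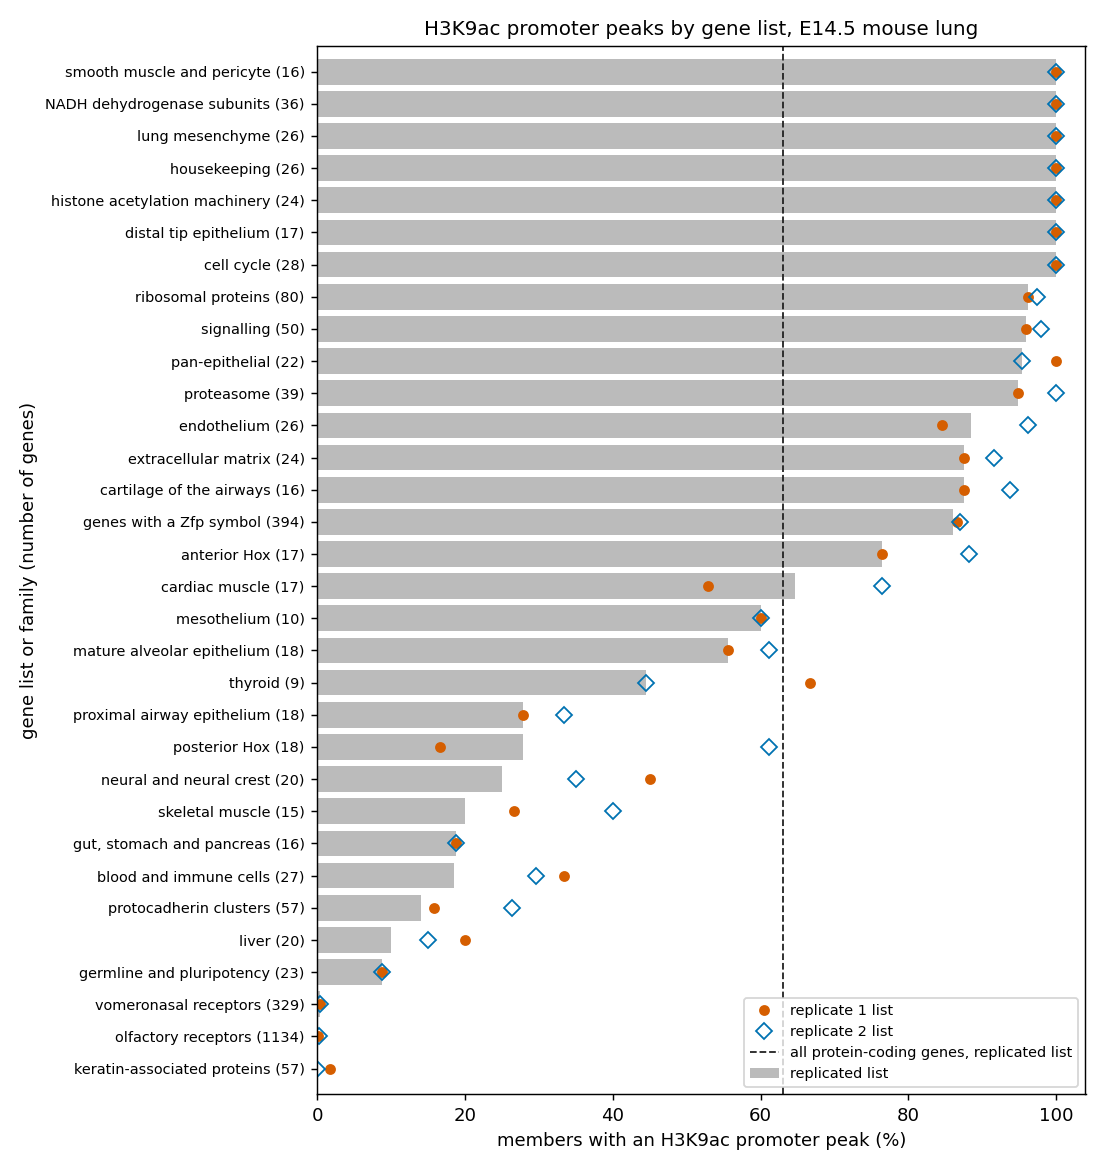
Share of the members of each gene list or family with an H3K9ac promoter peak, in percent on the horizontal axis, with the number of genes in parentheses. Grey bars show the replicated list, circles the list of replicate 1, diamonds the list of replicate 2, and the dashed line the 63.0% of all protein-coding genes; posterior Hox genes stand at 16.7% in replicate 1 and 61.1% in replicate 2.

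Hox genes, which pattern the body axis, were examined by their place in the clusters. Of 17 anterior Hox genes (paralogue groups at the 3′ side) 13 had a replicated promoter peak (adjusted p = 0.353, Fisher's exact test), with the highest values in the HoxA and HoxB clusters. Hoxa5 had 42.8 (35.6 and 43.6) in a peak at chromosome 6, 52197444 to 52207931, that also touched a start of Hoxa6. Hoxb3 had 32.4 (24.0 and 34.5) in a peak of 27.4 kb shared with Hoxb4 and Hoxb5. Hoxb1 and Hoxc6 had a peak in replicate 2 alone, at 4.98 and 3.32. The posterior list ran from the group of Hoxc8 and Hoxd8 to that of Hoxa13, and Hoxa7 stood in neither list. Of 18 posterior Hox genes 5 had a peak (adjusted exact p = 0.00375, lower), the strongest being Hoxd8 with 4.74 (4.64 and 5.27) and Hoxa10 with 4.07 (no peak in replicate 1 and 6.14 in replicate 2). This count depended on the replicate. Posterior promoters had a peak in 3 of 18 cases in the list of replicate 1 and in 11 of 18, or 61.1%, in that of replicate 2, where no difference from other genes was detected (adjusted exact p = 0.805). It was 50% in the pooled list (adjusted exact p = 0.248), and with peaks that touch a single gene, a setting added after the data were seen, the adjusted exact p was 0.0726. No posterior gene had a peak in replicate 1 only.

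**Figure D2:**
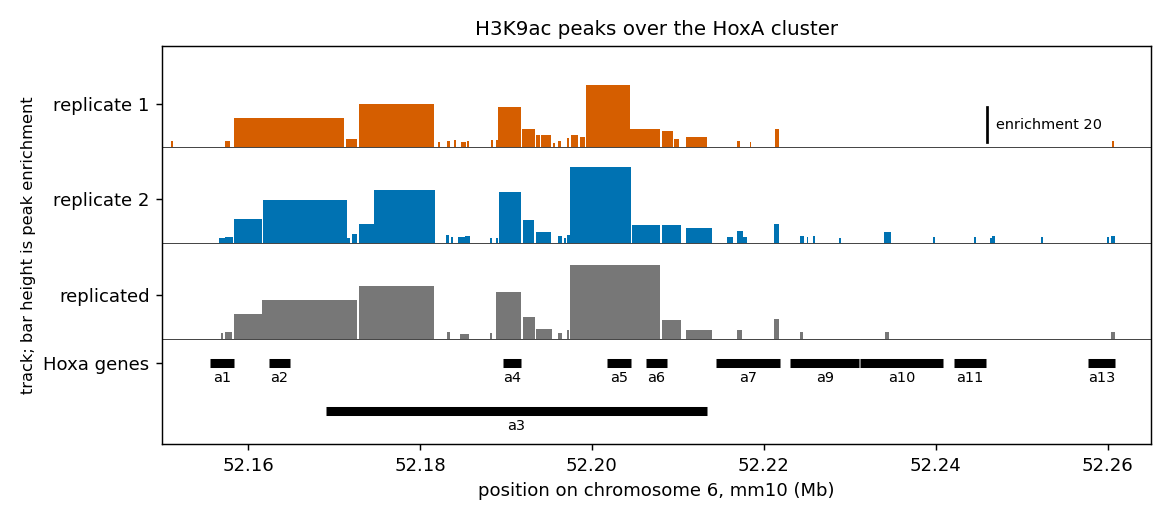
H3K9ac peaks over the HoxA cluster on chromosome 6 (mm10, Mb). Bars span each peak, with height proportional to its enrichment (scale bar, 20), for each replicate and the replicated list, above the Hoxa genes; the strongest peak, 42.8 in the replicated list, lies over Hoxa5, and the small peaks over Hoxa10 and Hoxa11 appear in replicate 2.

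In all, 13768 of 21853 protein-coding genes, or 63.0%, had a replicated promoter peak. In the lists of single replicates the numbers were 14064 and 14324, of which 13746 were shared, while 318 genes had a promoter peak in replicate 1 only and 578 in replicate 2 only. The strongest promoter peaks were those of Rbm39, an RNA-binding protein gene, with 60.3 (51.1 and 55.4), Nfib, a transcription factor needed for lung maturation, with 54.4 (46.1 and 53.3), Eif4a2, Srsf6, Actb with 51.2 (40.6 and 50.3), Clk1, Hmgb1, Rps19, Tnrc18 and Bicral with 49.5 (38.4 and 50.3). Genes active in most cells had promoter peaks with few exceptions: 28 of 28 cell cycle genes, 26 of 26 housekeeping genes, 24 of 24 genes of the histone acetylation machinery, 36 of 36 nuclear genes for mitochondrial NADH dehydrogenase, 77 of 80 ribosomal protein genes and 37 of 39 proteasome genes. All 6 shares exceeded that of other genes (highest adjusted p = 3.89e-05, Fisher's exact test). Examples were Cdk1 with 34.6 (30.3 and 31.3), Ep300, an acetyltransferase gene, with 41 (32.5 and 40.4), and Psmd1 with 32.9 (26.3 and 33.1). Members without a replicated peak were Rpl10l, Rpl39l and Rpl3l, which are variants of ribosomal protein genes, and the tissue-restricted proteasome genes Psma8 and Psmb11. Of 394 genes with a Zfp symbol 339 had a peak (odds ratio 3.69, adjusted exact p = 1.1e-23). At the other end stood olfactory receptors with 1 of 1134, vomeronasal receptors with 1 of 329, keratin-associated proteins with 0 of 57 and protocadherin clusters with 8 of 57 (adjusted exact p = 1.86e-13 for the last). The protocadherin share was 26.3% in the list of replicate 2, and 1 keratin-associated gene had a peak in replicate 1 and 1 further olfactory gene in replicate 2. The vomeronasal gene, Vmn1r4, shared its peak with Nt5c3, and the olfactory gene was Olfr94 with 4.24 (3.41 and 4.39). The call for NADH dehydrogenase genes was lost when peaks that touch several genes were left out, a setting added after the data were seen (20 of 36, adjusted exact p = 0.695).

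The share of genes with a promoter peak followed the CpG content of the promoter. It was 9.94% in the lowest tercile of observed over expected CpG, 82.5% in the middle and 96.6% in the highest, with median ratios of 0.177, 0.508 and 0.739. Within terciles 8 lists and families stayed or came to lie above other genes, against 14 without this stratification. The housekeeping (adjusted p = 0.220), cell cycle (adjusted p = 0.223), histone acetylation, ribosomal and proteasome lists were among those that no longer passed the stratified exact test. Every housekeeping, cell cycle and histone acetylation gene had a peak, the highest share possible. Even that share did not pass the stratified test, so no outcome could have called these lists higher, and it decides nothing for them. Full marking alone does not prevent a call, since the mesenchyme and smooth muscle lists, also fully marked, passed this test.

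Broad domains were found at most distal tip genes and many mesenchyme and signalling genes. The broad class began at a covered length of 3.89 kb and held 1091 genes. It took in 16 of 17 distal tip genes, against 7.82% of other genes with a promoter peak (odds ratio 188, 95% interval 29.2 to 7912, adjusted p = 1.07e-15, Fisher's exact test). It also took in 15 of 26 mesenchyme genes (odds ratio 16.0, interval 6.87 to 38.7, adjusted exact p = 9.65e-10), 10 of 13 anterior Hox genes (adjusted p = 1.67e-08), 23 of 48 signalling genes (odds ratio 10.9, adjusted p = 2.66e-12), 18 of 77 ribosomal protein genes (adjusted p = 0.000149) and 8 of 26 housekeeping genes (adjusted p = 0.00336). The longest were Foxf1, Hoxb3, Hoxb4, Nfib, Ptch1, Tbx5 and Tnrc18, whose window was covered over 10 kb, followed by Hoxa2 and Gata6 with 9.96 kb and Hoxa5 with 9.82 kb. Tbx4 had 8.92 kb, Nkx2-1 8.36 kb, Foxa2 7.49 kb and Sox9 4.66 kb. Of genes with a promoter peak, 1 of 21 pan-epithelial, 0 of 16 smooth muscle, 4 of 21 matrix and 4 of 23 endothelial genes were in the class (lowest adjusted exact p = 0.308). The matrix and endothelial shares, 19.0% and 17.4%, lay above the 7.91% of other genes but did not pass. With 10% of genes in the class, matrix genes (42.9%, adjusted exact p = 0.00997) and cell cycle genes (50%, adjusted exact p = 0.000133) passed. Cell cycle genes also passed with a window of 10 kb (25%, adjusted exact p = 0.0246). The housekeeping call was lost in the list of replicate 2 alone (23.1%, adjusted exact p = 0.0616), with the 5′ end of each gene only (adjusted p = 0.0742) and with a window of 10 kb (adjusted p = 0.465). The p of the anterior Hox list counts its genes as independent, although they lie in clusters. Hoxb3, Hoxb4 and Hoxb5 even lay under the same peak, so this p overstates the evidence.

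Of the replicated peaks 57.3% touched a promoter window, against a mean of 3.92% in random placements, a 14.6-fold difference (permutation test, p = 0.001, the smallest 1000 placements can give). The share was 38.8% in the list of replicate 1 (11.3-fold), 37.6% in that of replicate 2 (10.8-fold) and 42.8% in the pooled list (11.8-fold). The remaining 13012 replicated peaks were distal. Introns of protein-coding genes held 17.2% of replicated peaks, intergenic sequence 14.2%, exons 6.49% and starts of other kinds of genes 4.78%. Promoter peaks were stronger and wider than distal ones, with median enrichments of 11 and 3.71 and median widths of 1194 and 423 bp. The strongest distal peak, 60.4 (46.5 and 51.0) at chromosome 7, 73555929 to 73558615, covered the start of the non-coding gene 1810026B05Rik, 15.5 kb from Chd2. The next, 46.7 (36.8 and 47.4), lay at chromosome 10, 122983078 to 122987236, over Mirlet7i, which encodes a let-7 microRNA, and another of 44.7 (36.2 and 43.3) covered Snord104, a small nucleolar RNA gene, on chromosome 11.

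Distal peaks were more numerous around mesenchyme, signalling, distal tip and smooth muscle genes. These lists are not separate results, since genes such as Ptch1 stand in both the mesenchyme and the signalling list. Lung mesenchyme genes had 3.27 distal peaks each, 3.90 times the mean of matched random sets (adjusted p = 0.0024, permutation test), and signalling genes 2.92, or 3.75 times (adjusted p = 0.0024; both unadjusted p are 0.0002, the smallest 10000 sets can give). Distal tip genes had 3.35, or 3.53 times (adjusted permutation p = 0.0272), and smooth muscle genes 2.13, or 3.66 times (adjusted p = 0.0492). Extracellular matrix, anterior Hox and cell cycle genes stood at 2.75, 3.47 and 2.49 times but missed the threshold (adjusted permutation p = 0.0535 each), and no list lay below its matched sets. In the list of replicate 1, anterior Hox (2.94 times, adjusted permutation p = 0.028) and housekeeping genes (2.42 times, 0.025) lay above their matched sets and posterior Hox genes below them (0.0765 times, 0.025). In the list of replicate 2 these lists missed the threshold (2.07, 1.76 and 0.793 times, adjusted permutation p = 0.182, 0.182 and 0.890). Tbx3 had 11 distal peaks, Foxf1 8 and Ptch1 7. Most were assigned to Gse1 with 36, then to Sept9, Smad7 and Tns1 with 23 each, Cstad and Maml3 with 21 each, Bahcc1 with 20, Zfhx3 with 19, and 1700001O22Rik and Chd2 with 18 each. When random sets were drawn from genes with a promoter peak only, 2 of the 4 lists passed, and distal tip and smooth muscle genes did not (adjusted permutation p = 0.0672 each). Distal tip genes also missed it in the pooled list (2.86 times, adjusted permutation p = 0.0852). Smooth muscle was also lost in the list of replicate 1 alone (2.14 times, adjusted permutation p = 0.128), with windows of 2500 bp (0.095), 5′ ends only (0.0933) and q of 1e-05 or below (0.155).

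Whether the replicates shared peaks was asked next. Of the peaks of replicate 1, 53.6% were covered over at least 50% of their length by peaks of replicate 2, against 1.39% for random placements, a 38.6-fold difference. In the other direction the share was 46.2% against 1.25%, a 37.1-fold difference (permutation tests, p = 0.001 each, the smallest 1000 placements can give). By quintile of p within each list the share ran from 18.2% and 12.8% among the weakest peaks to 99.98% and 99.9% among the strongest. Across the 27818 replicated peaks touched in both replicates, Spearman's rho of the enrichments was 0.878, with 0.908 for promoter and 0.572 for distal peaks. Peaks are not independent replicates, so no p is given. Enrichments were within a factor of 2 for 97.0% of these peaks, and the median log2 ratio of replicate 2 to replicate 1 was 0.18.

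The replicated list kept 65.6% of the pooled peaks. Its peaks had a median enrichment of 5.49 and a median width of 725 bp, against 2.89 and 221 bp for the 16014 pooled peaks left out. Of the replicated peaks on the reference chromosomes 83.9% were covered over at least 50% of their length in both replicates, against 0.0125% of those left out, and 2648 touched no peak in at least one replicate. The authors derived the replicated list from the other lists, so this contrast in coverage follows at least in part from how the list was made.

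The replicates were compared by gene list. Over genes with a promoter peak in both replicates, the covered length of cardiac muscle genes had a median log2 ratio of 1.26 in favour of replicate 2, above all 10000 matched gene sets, with 8 of 9 genes longer in replicate 2. Smooth muscle genes had a median of 0.54, also above all matched sets, with 14 of 16 longer. The 5 blood and immune genes with a promoter peak in both replicates had a median of -0.28, at percentile 0.655, with 2 of 5 longer in replicate 2. Housekeeping genes (percentile 1.94) and the 5 proximal airway genes (percentile 98.2, with 3 of 5 longer in replicate 2) also lay outside the middle 95%, while all 18 proximal airway genes lay inside it by the difference in mean covered length (percentile 55). By gene, chosen after their values were seen, Gata4 was covered over 2212 bp in replicate 1 and 6417 bp in replicate 2, Hand2 over 1063 and 4841 bp and Tbx20 over 1542 and 3690 bp. Slc4a1, the anion exchanger of red blood cells, was covered over 4236 bp in replicate 1 and 56 bp in replicate 2. By enrichment, the measure set beforehand, cardiac genes lay at percentile 92.9 and blood genes at 78, inside the middle 95%, while anterior Hox genes (median log2 ratio 0.52, percentile 99.98) and cell cycle genes (0.13, percentile 0.83) lay outside it. Anterior Hox genes lay inside it by the p of the peaks (percentile 80.4) and by the median ratio of covered length (percentile 50.7), and cell cycle genes by that of covered length (percentile 24.3) but not by p (percentile 0.67). The anterior Hox median by enrichment is the ratio of Hoxb3 and Hoxb4, which have the same values (24.0 and 34.5 in replicates 1 and 2). The matched sets took no account of peaks shared by neighbouring genes, so the anterior Hox percentile is overstated. By mean covered length over all 17 members, a comparison chosen after the data were seen, anterior Hox genes had 4.80 kb in replicate 1 and 5.25 kb in replicate 2, outside the middle 95% (percentile 99.0). The libraries come from 1 pool each, so these differences have no test.

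**Figure D3:**
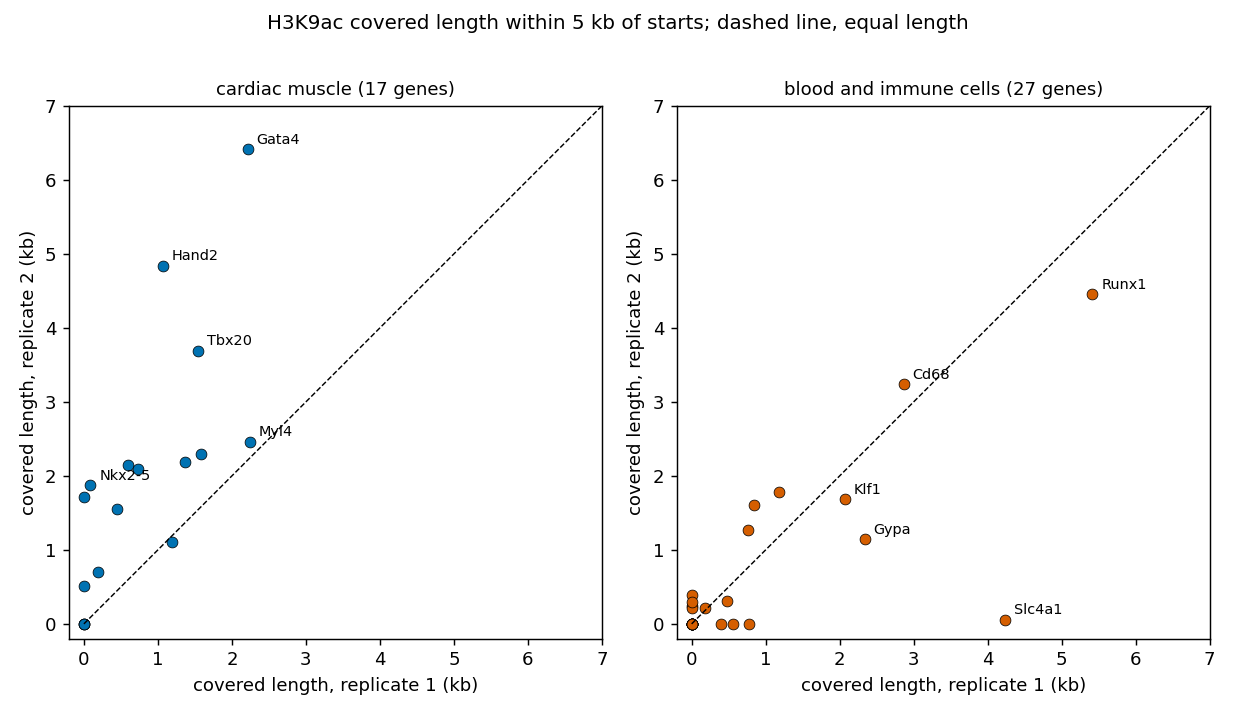
Covered length (kb) by H3K9ac peaks within 5 kb of a transcript start in replicate 1 (horizontal axis) and replicate 2 (vertical axis), 1 point per gene, for 17 cardiac muscle genes and 27 blood and immune genes. Gata4, Hand2 and Tbx20 lie above the dashed line of equal length, and Slc4a1 lies far below it.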

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

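The tests on neighbouring starts and on posterior Hox promoters were chosen after the counts they use, or counts that made their outcome foreseeable, had been seen. The second gene lists were composed after the patterns in the first lists had been seen, and hold none of the same genes.

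Signal lay outside the protein-coding genes and reference chromosomes that the main comparisons use. Starts of 471 lincRNA genes that lie away from protein-coding starts had a replicated peak. A further 6 replicated peaks lay on sequences outside the 21 reference chromosomes, the strongest with an enrichment of 15.

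The first pattern is the longer coverage at heart muscle genes in replicate 2 and at red blood cell genes in replicate 1, although in the first blood and immune list 9 genes were longer in replicate 2 and 8 in replicate 1, with Slc4a1, chosen after its values were seen, covered over 4236 and 56 bp. In a second list of 34 heart muscle genes the mean covered length was 0.753 kb in replicate 1 and 1.08 kb in replicate 2. Of these genes 20 were longer in replicate 2 and 8 in replicate 1, at percentile 100 of sets matched on covered length. This argues against a gain shared by all genes of similar covered length. The sets were not matched on enrichment, so weak peaks called more readily in replicate 2 remain open. More heart muscle cells in that pool could also give the difference. The first and second skeletal muscle lists, at percentiles 36.3 and 50.9, lent striated muscle of any kind no support. Both lay inside the middle 95% and did not exclude it. In a second list of 28 red blood cell genes the mean was 2.19 kb in replicate 1 and 1.56 kb in replicate 2, with 24 genes longer in replicate 1 and 1 in replicate 2, at percentile 0, which is consistent with more red blood cells in the pool of replicate 1. The difference was not specific to these cells: 12 of 28 lists lay outside the middle 95% with no correction for their number, among them smooth muscle and posterior Hox genes (percentile 100 each) and a second hepatocyte list (0.14), while the first liver list lay at 49.9. Of the second lists 17 heart muscle and 21 red blood cell genes had a replicated promoter peak, the labels name no sort, and of abundant genes Tnnt2, chosen after its values were seen, was covered over 0 bp in replicate 1 and 1714 bp in replicate 2 and Hba-a1 over 391 and 0 bp, so heart tissue in the dissection, muscle that belongs to the lung, blood in vessels and liver tissue all remain open.

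The second pattern is that 16 of 17 distal tip genes lie in the broad class. The share lay at percentile 100 of gene sets matched on the CpG count within 5 kb, whose mean was 32.4%, and at percentile 100 of sets matched on the number of annotated starts, whose mean was 7.18%, which argues against either as the whole cause. Among genes with no other protein-coding start within 10 kb, 15 of 16 tip genes and 5.95% of other genes were in the class (Fisher's exact test, p = 7.73e-18), which argues against neighbouring protein-coding starts as the whole cause. Neighbouring starts of non-coding genes were not examined and remain open. No biological explanation was tested, since the design holds a single tissue and stage.

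The third pattern is the posterior Hox promoters with a peak in replicate 2 and none in replicate 1. Of the 15 posterior genes without a peak in replicate 1, 8 gained one, against a mean of 3.35 in sets matched on promoter CpG content (percentile 99.5) and 7.42% of all genes without a peak in replicate 1. The list was singled out for this gain, and its genes lie together in clusters, which the matching did not take into account. The percentile therefore does not decide whether a general gain at CpG-rich promoters was the whole cause, and such a gain could account for part of the count. Whether the pools differed in the tissue taken along the body axis was not tested.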

How the results depend on the processing

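Alternatives restricted to complete transcript starts and to peaks that touch a single gene were chosen after the data were seen; the others were planned. For the 16 values that answer a comparison, 93 of 124 alternative values stayed within the limit for their kind (the side of the threshold for a test, 1.5 times for a count, the spread or interval for other values). Overlap between replicates and the promoter share of peaks were judged against random placements only, so wide changes counted as within the limit. The shared part of replicate 1 peaks ran from 41% with a reciprocal overlap of 50% to 91.4% at q of 1e-05 or below. For replicate 2 peaks it ran from 38.6% to 75.6% at the same settings. The promoter share ran from 37.6% in the list of replicate 2 to 72.8% at q of 1e-05 or below. The number of lists above other genes at promoters was 14 to 15 apart from CpG terciles (8). The share of pooled peaks kept was 60.9% with an overlap of 1 bp in place of the authors' list and 79.1% at q of 0.01 or below. With 10% of genes in the broad class, 1 list lay below other genes, the genes with a Zfp symbol (9.44%, adjusted exact p = 0.00332), which stood slightly above them in the main class. Lists above matched sets by distal peaks numbered 7 with 5′ ends only, 7 within 50 kb and 2 among genes with a promoter peak, and lists below numbered 0 to 1 without one replicate. The ratio of promoter to distal median enrichment, 2.96, was 3.18 at 500 bp, 2.5 at 2500 bp, 3.20 with 5′ ends and 2.61 at q of 1e-05 or below, and 2.39 to 2.63 without one replicate. That of widths, 2.82, was 2.96, 2.47, 2.76 and 2.16 in the same order, 3.73 in the pooled list, 2.77 at q of 0.01 or below and 3.57 to 3.64 without one replicate. The difference in marked share between the highest and lowest CpG terciles, 86.7 percentage points, was 68.1 by GC content, 88.8 at 500 bp and 83.6 to 84.2 without one replicate. Agreement between replicates was 0.886 by p, 0.908 for promoter and 0.572 for distal peaks. By p 1 list stood apart between replicates and by covered length 5, against 2 by enrichment; anterior Hox genes were lost by both and cell cycle genes by the median ratio of covered length, although anterior Hox genes stood apart by mean covered length over all members (percentile 99.0). The cause was not tested. Of values for single genes, 30 of 1092 moved under other settings and 110 of 312 without one replicate. Depth is unknown, so the lack of a peak was not read as the lack of the mark.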

Other observations

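The comparisons in this part were chosen after the peak lists had been seen. Non-coding genes carried some of the strongest peaks. Among gene types, starts of 91.6% of the 190 genes annotated as bidirectional-promoter lncRNAs had a replicated peak, as did 50.1% of processed transcripts, 34.2% of antisense genes and 14.1% of lincRNA genes, against 1.20% of processed pseudogenes. Of starts away from protein-coding ones, 24.7% of 442 processed transcripts, 10% of 1834 antisense genes and 8.73% of 5396 lincRNA genes had a peak. Only 1 of the bidirectional-promoter lncRNA genes lay away from protein-coding starts, and it had no peak. Strong examples, chosen after their values were seen, were Snhg6, a host of small nucleolar RNAs, with 39.3 (31 and 39.5 in replicates 1 and 2), and Mir17hg, host of the miR-17 cluster, with 37.6 (29.4 and 38.6) at chromosome 14, 115040101 to 115043142. Tug1 had 32.4 (27.2 and 31) and Dancr 31.9 (26.45 and 32). Antisense genes within the Hox clusters, Hoxaas3 with 42.8 (35.6 and 43.6) and Hoxb5os with 32.4 (24.0 and 32), lay under the same peaks as Hoxa5 and Hoxb5.

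Of the 10 strongest distal peaks, 1 touched no annotated start of any gene: chromosome 15, 85669637 to 85673364, with 38 (31.9 and 41), 64.1 kb from the nearest protein-coding start, that of Ppara. Genes with a distal peak assigned had a promoter peak in 84.7% of cases and other genes in 55%. Chromosome X had a promoter peak at 44.3% of its 948 protein-coding genes, and chromosome Y at 4 of 183, while the autosomes ranged from 50.6% on chromosome 14 to 76.2% on chromosome 12. Of 57 protocadherin cluster genes the strongest was Pcdhgc3 with 20.2 (16.3 and 21), followed by Pcdhac2 with 6.59 (6.19 and 7.90), both C-type members.

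Further lists gave values for the replicate difference in mean covered length over all members. Posterior Hox genes were covered over 0.0956 kb in replicate 1 and 0.548 kb in replicate 2, a gain above all matched sets. Cartilage genes gained 0.383 kb (percentile 99.5), endothelial genes 0.339 kb (percentile 99.0), anterior Hox genes 0.453 kb (percentile 99.0) and housekeeping genes -0.0747 kb (percentile 0.4). Distal tip genes, with 7.06 and 7.20 kb (percentile 23.8), and lung mesenchyme genes, with 4.93 and 5.14 kb (percentile 50.9), lay inside the middle 95%.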
